A study of Mus musculus with 9 samples.

How the data were processed

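Total RNA from 9 samples of cultured mouse fibroblasts, in 3 groups of 3, had been extracted with a commercial kit and sequenced on an Illumina instrument, per the labels' protocols and the series' design text. The deposited values are raw read counts per Ensembl gene, whole numbers with no normalisation, and the authors' table of the whole series held the same counts as the files of the single samples (0 cells differed). Per the submitters' processing notes, bcl2fastq, TopHat and edgeR were used with build mm10, with no versions named. The read counter, its strand setting and the gene annotation are not given in the sources used here. Reads of genes with near-identical copies, such as ribosomal protein and histone genes, could have been lost or split in counting, so those genes are uncertain.

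Groups came from the source and genotype labels, and replicates were numbered in the order of the records, so the numbers pair no samples. Gene symbols were matched by Ensembl ID for 51633 of 51912 genes, and coordinates came from GENCODE release M21 on GRCm38, the assembly behind mm10. Counts totalled 15433810 to 21893574 per library, and 3 counts, used as the floor, correspond to 0.128 to 0.193 CPM in single libraries. Floors and counting intervals (95%, exact binomial) cover counting error only. The transcript Gm42418, which overlaps ribosomal RNA, took 1.01% to 5.34% of the counts.

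Genes were kept with edgeR 4.0.16 filterByExpr (14314 genes), scaled by TMM, and tested in 1 quasi-likelihood fit of all 9 samples with group as the only term, in R 4.3.3. P-values were adjusted by the Benjamini-Hochberg method and called under 0.05. Standard errors of log2 fold changes came from the F statistic. CPM values use TMM library sizes, and means carry the SD of 3 libraries. A fold against a group with no counts was computed against 3 counts over the group and is a lower bound. Folds of this kind, group means, called members of lists and lists with an estimated correlation were also computed without each library, a choice made after seeing the data, and are given where a call changed or the value moved by over 1.5 times, for folds where a library of the group with counts, or the one holding the few counts, moved them. Of counts adjusted over a list alone, only those of the interferon list are given without single libraries. Leaving out a library of the group with no counts lowered a bound by 1.40 to 1.73 times through the loss of depth. Ctnnb1 also had an exact permutation test. The 39 gene lists, covering pathways, markers of other cells and RNA quality, were written before the data were examined, as were the designs, the rule for named genes and most alternatives. Lists with at least 5 tested members were tested with camera in limma 3.58.1, with a preset correlation of 0.01; with all libraries, no list stayed under 0.05 with an estimated correlation. fry gave a further test.

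Named genes were Ctnnb1, the 10 largest log2 fold changes in each direction of each main comparison among called genes with mean CPM of at least 5 and all 3 libraries of a group above all 3 of the other, leaving out model names. None qualified for the labelled-deficient libraries against NF. Up to 4 called members of each described list, the 5 largest reversals in each direction, Wnt target and myofibroblast genes, and the most abundant marker of each other cell type could also be named. Members named because few of their list moved one way, the genes called against NF by other tools, mt-Nd4, mt-Co1, Mtap, Xist, the Y-linked genes read per library and the Cdkn2a region were chosen after their values were seen. Alternatives were RLE scaling, no filter, a filter of CPM of at least 1 in 3 samples, DESeq2 1.42.0, limma-voom, only the 6 samples compared, a test beyond 1.5-fold and leaving out each library. Total counts as the scaling and counts without Gm42418 were added after seeing the data. Pseudocount alternatives apply to normalised values and were not run.

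The scripts were tested on simulated counts drawn from the real means, library sizes and dispersions, with 100 genes changed by each of 2 sizes in each comparison and 1 list shifted. For CAF against NF, 28% of genes changed by a log2 of 1 and 77% changed by a log2 of 2 were recovered. For the labelled-deficient libraries the values were 26% and 82% against CAF, and 28% and 81% against NF. Of the unchanged genes that passed the filter, 7 of 13723, 10 of 13689 and 12 of 13748 were called in these comparisons. The shifted list was recovered with 0 other lists called. Simulated genes were drawn independently of each other, so that count of 0 cannot test list calls that depend on correlation between genes.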

Results

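RNA from cultured mouse fibroblasts was sequenced in 3 groups of 3 libraries. One group was normal fibroblasts (NF), another was cancer-associated fibroblasts (CAF), which are fibroblasts of the tumour stroma, and the last was cancer-associated fibroblasts labelled beta-catenin-deficient (bcatKO_CAF). The strain was C57BL/6, and the cells were kept in DMEM with serum. Deposited read counts covered 51912 genes, with totals of 15433810 to 21893574 counts per library, and 14314 genes were tested. Nothing in the labels says that replicates came from separate cultures or animals, so p-values measure only the spread between these samples, which may be technical.

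Ctnnb1, which encodes beta-catenin, the adhesion and Wnt signalling protein named in the genotype label, was transcribed in every library. Its level was 855, 882 and 858 CPM (read counts scaled to a common library size) in CAF replicates 1 to 3 and 668, 637 and 627 CPM in the libraries labelled beta-catenin-deficient. In NF it was 713, 799 and 669 CPM. The gene lies on chromosome 9 from 120929216 to 120960507 (GRCm38). Relative to CAF, the log2 fold change in the labelled-deficient libraries was -0.43 ± 0.14 (SE), which is 74.4% of the CAF level, with an edgeR quasi-likelihood adjusted p of 0.0339, and all 3 of these libraries lay below all 3 CAF libraries. Such a separation held for 65.7% of all tested genes in this comparison, and the median absolute log2 fold change of all tested genes was 0.61. The lower level of Ctnnb1 thus did not stand out among genes. The exact two-sided permutation p of the 3 against 3 values was 0.1, the smallest this design allows. It was also 0.1 for CAF against NF and for the labelled-deficient libraries against NF. Against NF the log2 fold change was -0.17 ± 0.14, with an adjusted p of 0.620. Counts per gene include reads from any exon outside a deletion, so this level does not check the genotype label. With total counts as the scaling, a choice made after seeing the data, the log2 fold change against CAF was -0.29 (adjusted p = 0.152), without a filter it was -0.41 (adjusted p = 0.160), and leaving out any 1 library of the comparison also ended the call, with adjusted p from 0.0665 to 0.115.

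The CAF libraries stood apart from the other 6. Across genes, log2 CPM values of the 3 CAF libraries correlated with each other at Pearson r from 0.982 to 0.986, and with NF libraries at 0.776 to 0.792. NF and labelled-deficient libraries correlated at 0.922 to 0.989, and NF libraries with each other at 0.935 to 0.970. NF replicate 1 correlated at 0.951 with NF replicate 2 and at 0.935 with NF replicate 3, but at 0.984 to 0.989 with the labelled-deficient libraries. The sex, the animal and the site of origin of the cells are not given in the sources used here, for any group. Genes are not independent replicates, so these values describe the libraries only. The chi-square value per gene was at least 20.4 in every pair of libraries, so none agreed within sampling noise.

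**Figure D1:**
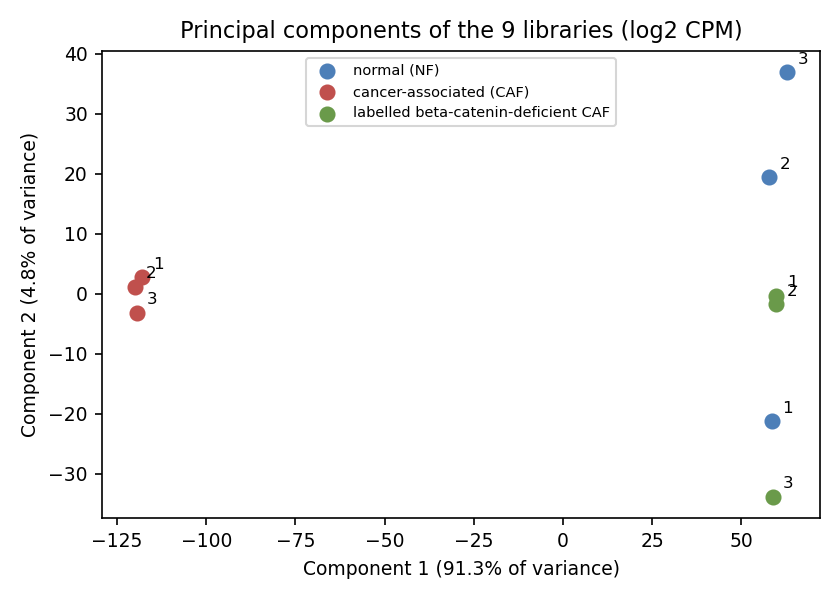
Principal components of log2 CPM values of the 1000 most variable genes, with 1 point per library, coloured by group and numbered by replicate. Component 1 held 91.3% of the variance and separated the 3 CAF libraries (-120.0 to -118) from the other 6 (57.8 to 62.8).

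Between CAF and NF, 22 of 25 myofibroblast genes, 15 of 20 collagens and 25 of 40 matrix glycoproteins were higher in CAF. Camera called these 3 lists with the preset correlation and not with an estimated correlation (adjusted p = 0.0616, 0.216 and 0.0783 with the latter). Thy1, a surface marker of fibroblasts, was at 1960.2 ± 217 CPM (SD, n = 3) in CAF and 0.389 ± 0.309 in NF. Tagln, an actin-binding protein of smooth muscle, reached 2727 ± 484 CPM against 0.744 ± 0.219, and Acta2, smooth muscle actin, reached 5059 ± 844 against 3.27 ± 3.14, or 1.48 without NF replicate 1. Spp1, which encodes osteopontin, was lower, at 759 ± 256 CPM in CAF and 7654 ± 2121 in NF. In all, 2866 genes were higher and 2847 lower in CAF at an adjusted p under 0.05, of which 2120 and 1853 changed by an absolute log2 fold change of at least 1.

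Of 25 tested myofibroblast genes, 22 rose and 0 fell in CAF, and 3 did not pass the test (22 higher and 0 lower adjusted over the list alone). Their median log2 fold change was 4.56, with camera adjusted p = 1.73e-11, and adjusted p = 0.0616 with an estimated correlation. Without CAF replicate 3 the list was also called with an estimated correlation (adjusted p = 0.0167). Myl9, a myosin light chain, had a log2 fold change of 11.79 ± 0.50 (SE, adjusted p = 6.60e-07). Itga11, an integrin that binds collagen, was higher by 6523-fold (95% counting interval 1805 to 53867). Markers of pericytes and smooth muscle moved with these genes, with 5 of 10, Mcam, Abcc9, Myh11, Lmod1 and Ndufa4l2, higher and 2, Cspg4 and Rgs5, lower (6 higher and 2 lower adjusted over the list alone, with camera adjusted p = 0.0143, and adjusted p = 0.216 with an estimated correlation). Lmod1, an actin nucleator of smooth muscle, was at 126 ± 15.5 CPM in CAF and 0.161 ± 0.0345 in NF, Myh11, smooth muscle myosin, at 56.1 ± 31.9 and 0.181 ± 0.137 (0.114 without NF replicate 1), Mcam at 92.4 ± 10.0 and 5.37 ± 1.21, and Cspg4 at 92.2 ± 7.92 and 400.2 ± 352, or 199 in NF without replicate 1. The call of Rgs5 was lost without CAF replicate 2 or 3 or NF replicate 2 (adjusted p = 0.0845, 0.0699 and 0.0711). Among the collagens, 15 of 20 rose and 1, Col18a1, fell (15 higher and 2 lower adjusted over the list alone, with camera adjusted p = 6.18e-06, and adjusted p = 0.216 with an estimated correlation). Without CAF replicate 2 or NF replicate 1, 2 collagens were lower. Col1a1 stood at 19927 ± 5611 CPM in CAF and 149 ± 66.5 in NF, Col1a2 at 11915 ± 2305 and 173 ± 158, and Col12a1 at 5075 ± 135 and 37.1 ± 30.8. Without NF replicate 1, the NF means were 82.5 for Col1a2 and 20.1 for Col12a1. Of 40 matrix glycoproteins, 25 rose and 4, Ltbp3, Tgfbi, Lamb1 and Ecm1, fell (26 higher and 5 lower adjusted over the list alone, with camera adjusted p = 7.85e-07, and adjusted p = 0.0783 with an estimated correlation). The call of Lamb1 was lost without CAF replicate 1, 2 or 3 or NF replicate 1 or 2, with RLE scaling and with only the 6 samples compared (adjusted p = 0.0543 to 0.139). Fmod, a small proteoglycan, had no count in NF and was at least 477-fold higher in CAF, against a floor of 3 counts over the group. The collagen crosslinkers Lox and Loxl2 were at 3277 ± 65.7 and 729.9 ± 152 CPM in CAF, and at 5.19 ± 1.64 and 0.602 ± 0.527 in NF, where Loxl2 was at 0.319 without replicate 3.

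Of the Wnt pathway members, 23 of 45 were higher in CAF and 5, Wnt7b, Wnt10a, Fzd5, Fzd9 and Csnk1a1, lower (23 higher and 7 lower adjusted over the list alone, with camera adjusted p = 1.72e-04, and adjusted p = 0.105 with an estimated correlation). The 5 lower ones became 3 without CAF replicate 2 and 2 without CAF replicate 3. The call of Wnt10a was lost without CAF replicate 2 or 3 (adjusted p = 0.0522 to 0.0551), that of Fzd9 without CAF replicate 1 or 3 and with only the 6 samples compared (adjusted p = 0.0732 to 0.106), and that of Csnk1a1 without CAF replicate 1, 2 or 3 or NF replicate 1 or 3, with RLE scaling, with only the 6 samples compared and without a filter (adjusted p = 0.0551 to 0.160). The ligand Wnt5a was at 373 ± 28.0 CPM in CAF and 0.386 ± 0.122 in NF, the secreted protein Dkk3 at 175 ± 13 and 0.168 ± 0.0973, and the receptor Fzd2 at 181 ± 35.6 and 4.50 ± 1.20. The ligand Wnt7b went the other way, at 0.530 ± 0.0806 CPM in CAF and 95.7 ± 85.8 in NF, or 49.7 without NF replicate 2. Genes known as Wnt targets moved both ways, with 7 higher and 6 lower of 19. Adjusted over the list alone, 7 were higher and 6 lower, and camera gave an adjusted p of 0.701. The fry test called the list higher in CAF (adjusted p = 0.00894), as 1 of 28 called among 36 lists. Ccn4 and Prickle1 rose, with log2 fold changes of 7.87 ± 0.56 and 8.05 ± 0.34 (SE), while Notum, Tcf7 and Ccnd1 fell, with -8.94 ± 0.70, -5.53 ± 0.26 and -2.70 ± 0.22. Axin2, a widely used reporter of the pathway, was at 1.04 ± 0.337 CPM in CAF and 2.75 ± 1.74 in NF (adjusted p = 0.0932), and passed the test without NF replicate 1 (adjusted p = 0.0102). Of 23 cadherin and catenin genes, 14 rose and 4, Cdh6, Cdh13, Pkp1 and Afdn, fell (14 higher and 5 lower adjusted over the list alone, with camera adjusted p = 0.0139, and adjusted p = 0.216 with an estimated correlation). The call of Afdn was lost without CAF replicate 1 or 2 or NF replicate 3, with only the 6 samples compared and without a filter (adjusted p = 0.0506 to 0.0721). Cdh11, a mesenchymal cadherin, was at 1094 ± 147 CPM in CAF against 5.31 ± 6.70 (1.44 without NF replicate 3), and Cdh6 at 2.17 ± 1.72 against 163 ± 41.3.

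Cholesterol synthesis genes rose together, 21 of 25 higher and 0 lower (22 higher and 1 lower adjusted over the list alone, with camera adjusted p = 3.82e-08, and adjusted p = 0.328 with an estimated correlation). Without NF replicate 1, 1 of them was lower. Hmgcs1, an early enzyme of the pathway, was at 657 ± 133 CPM in CAF and 79.6 ± 27.7 in NF. Feedback genes of MAP kinase signalling went down in 14 of 21 cases and up in 3, Spry1, Epha4 and Il1rl1 (3 higher and 16 lower adjusted over the list alone, with camera adjusted p = 4.54e-04, and adjusted p = 0.216 with an estimated correlation), with Etv1 at 6.44 ± 1.61 CPM in CAF and 105 ± 35.3 in NF. Of 50 G2 and mitosis genes, 24 rose and 1, Anp32e, fell (25 higher and 1 lower adjusted over the list alone, with camera adjusted p = 8.36e-05, and adjusted p = 0.562 with an estimated correlation), among them Kif20a at 171 ± 7.46 against 44.3 ± 10.7 CPM. The list mean was 5.91, 4.87 and 5.04 log2 CPM in NF replicates 1 to 3 and 5.96 to 6.06 in CAF, and the median log2 fold change went from 0.68 to 1.23 without NF replicate 1. Without that library 43 of the genes were higher, and without any other single library of the comparison 13 to 15. Genes of the G1 to S transition leaned the other way, with 4 of 46 higher and 12 lower (3 and 11 adjusted over the list alone). Camera gave that list an adjusted p of 0.0529, or 0.606 with an estimated correlation. It was called lower without CAF replicate 1, NF replicate 1 or NF replicate 3, and with total counts (adjusted p = 0.0216 to 0.0382). HOX genes, which mark position along the body axis, rose in 25 of 26 cases (25 higher and 0 lower adjusted over the list alone, with camera adjusted p = 2.84e-14, and adjusted p = 0.0707 with an estimated correlation), with a median log2 fold change of 4.80, also 4.80 with 4 members at their bound. Hoxc8, Hoxc9 and Hoxc10 had no count in NF and were at least 1107-fold, 473-fold and 685-fold higher in CAF. The Y-linked gene Ddx3y was at 18.4, 84.9 and 120.4 CPM in CAF replicates 1 to 3 and at most 0.185 CPM in NF. Xist, transcribed from the inactive X chromosome, was at 257, 0.155 and 4.92 CPM in CAF replicates 1 to 3 and 283 to 861 CPM in NF. It passed the test only without CAF replicate 1 among the settings run (adjusted p = 0.00208, against 0.214 with all libraries).

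Among lists kept as signs of RNA quality, 5 of 10 histone genes, Hist1h1c, Hist1h2bc, Hist1h4i, Hist2h3c2 and H2afx, were higher in CAF than NF and 0 lower (5 higher and 0 lower adjusted over the list alone, with camera adjusted p = 0.0740, and adjusted p = 0.328 with an estimated correlation). Camera called this list without NF replicate 3 (adjusted p = 0.0495) and with total counts (adjusted p = 0.0485), and without NF replicate 2 3 members were higher. With an estimated correlation the adjusted p without NF replicate 3 was 0.425. The call of Hist2h3c2 was lost without CAF replicate 1, 2 or 3 or NF replicate 2 and with only the 6 samples compared (adjusted p = 0.0574 to 0.0636), and that of H2afx without CAF replicate 2 or NF replicate 2, with only the 6 samples compared and with total counts (adjusted p = 0.0514 to 0.0698). Of 20 immediate early genes, which respond quickly to stress and handling, 7 were higher and 5, Fosb, Jun, Egr3, Atf3 and Klf4, lower (7 higher and 5 lower adjusted over the list alone, with camera adjusted p = 0.231, and adjusted p = 0.328 with an estimated correlation). The lower ones became 3 without CAF replicate 1 and 2 without CAF replicate 2. The call of Fosb was lost without CAF replicate 1 or 2 (adjusted p = 0.0549 to 0.0616), that of Klf4 without CAF replicate 2 (adjusted p = 0.0533), and that of Atf3 without CAF replicate 1, 2 or 3 or NF replicate 1 and with only the 6 samples compared (adjusted p = 0.0596 to 0.116). Of 50 ribosomal protein genes, 1, Rplp1, was higher and 4, Rpl3, Rpl10a, Rps13 and Rps27a, lower (0 higher and 0 lower adjusted over the list alone, with camera adjusted p = 0.862, and adjusted p = 0.975 with an estimated correlation). The lower ones became 1 without CAF replicate 2 or 3 or NF replicate 2, and 2 were higher without NF replicate 1. The call of Rpl3 was lost without CAF replicate 1, 2 or 3 or NF replicate 2, with only the 6 samples compared and without a filter (adjusted p = 0.0731 to 0.128), that of Rpl10a without CAF replicate 1, 2 or 3 or NF replicate 1 or 2, with RLE scaling, with DESeq2, with only the 6 samples compared and without a filter (adjusted p = 0.0584 to 0.139), and that of Rps27a without CAF replicate 2 or 3 or NF replicate 2, with RLE scaling and with only the 6 samples compared (adjusted p = 0.0501 to 0.156). The median of this list was 0.03, or -0.13 with total counts. Of 13 protein-coding genes of the mitochondrial genome, only 7 passed the filter and were tested. Of these 7, edgeR called 0 higher and 0 lower, also adjusted over the list alone. Camera gave an adjusted p of 0.293, or 0.728 with an estimated correlation. The unadjusted edgeR p was under 0.05 for 2, mt-Nd4 and mt-Co1 (adjusted p = 0.0520 and 0.0987), both lower in CAF. Of these, mt-Nd4 was called with DESeq2 and without a filter (adjusted p = 0.0352 and 0.0207), and both were called with total counts (adjusted p = 0.0249 and 0.0433). Without NF replicate 3, 4 of the 7 mitochondrial genes were lower, with camera adjusted p = 0.0377, and adjusted p = 0.319 with an estimated correlation.

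Interferon-response genes were not called as a list between CAF and NF (camera adjusted p = 0.759), with 1 of 43, Ifi27l2a, higher and 7 lower. Adjusted over the list alone, 0 were higher and 0 lower. The call of Ifi27l2a was lost without CAF replicate 2 (adjusted p = 0.0530). Ifit3, an antiviral protein, was at 221, 45.2 and 5.91 CPM in NF replicates 1 to 3, and at 5.04 to 16.6 CPM in CAF. Its adjusted p of 0.0331 became 0.144 without NF replicate 1, 0.111 without CAF replicate 1 and 0.117 without CAF replicate 2. With only the 6 samples compared it was 0.0622. Without NF replicate 3, the list was called lower in CAF with the preset correlation (camera adjusted p = 0.00494) and not with an estimated correlation (adjusted p = 0.773), with 1 gene higher and 16 lower, also adjusted over the list alone. The balance turned without NF replicate 1, with 8 higher and 1 lower, or 2 and 0 adjusted over the list alone, and the median log2 fold change went from -0.62 to 0.67. Without CAF replicate 1, 2 or 3, 1, 0 and 3 genes were lower and 2, 0 and 1 higher, and adjusted over the list alone 0 were higher and 0 lower in each case.

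The named gene with the largest fitted log2 fold change in CAF was Adcyap1r1, a receptor of the peptide PACAP, absent from the counts of NF and at 79.0 ± 35.8 CPM in CAF, or at least 1431-fold higher. Cd55, an inhibitor of complement, was at least 1172-fold higher, and the transcription factor gene Dmrt2 at least 621-fold. Cdh3 and Irx1 were higher by 6595-fold (95% counting interval 1183 to 260526) and 6467-fold (95% counting interval 1160.3 to 255471). Cdh3 was at least 1554-fold higher without NF replicate 3, and Irx1 at least 1245-fold without NF replicate 2. Rps4l was at 44.8 ± 9.54 CPM in CAF with no count in NF, an uncertain value because it is annotated as a processed pseudogene that can share reads with its parent gene. Among genes lower in CAF, Dmp1, a bone matrix protein, had no count in CAF and was at least 807-fold lower, Insm1 at least 734-fold, Cxcr3 at least 582-fold, Sucnr1 at least 535-fold, Rasgrf1 at least 452-fold, Serpina3m at least 569-fold and Cxcr4 at least 552-fold. Several of these limits rested on 1 NF library. Without NF replicate 2 they were 429-fold for Insm1, 129-fold for Serpina3m and 173-fold for Cxcr4. Without NF replicate 3 they were 252-fold for Cxcr3 and 190.1-fold for Rasgrf1, and without NF replicate 1 the limit for Sucnr1 was 289.8-fold. Aldh3a1 and Slc9a2 fell from 379 ± 363 and 318 ± 192 CPM in NF to 0.101 ± 0.0437 and 0.0891 ± 0.0802. The NF mean of Aldh3a1 was 173 CPM without NF replicate 2, and the CAF mean of Slc9a2 was 0.0560 without CAF replicate 2 and 0.134 without CAF replicate 3. Tmprss11b was lower by 4767-fold (95% counting interval 1631 to 23120.2), or at least 3049-fold without CAF replicate 3.

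Under total counts as the scaling, added after seeing the data, the median log2 fold change of all genes moved from -0.04 to -0.20, and 2440 genes were called higher and 3701 lower. Requiring a change beyond 1.5-fold left 3583 genes.

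**Figure D2:**
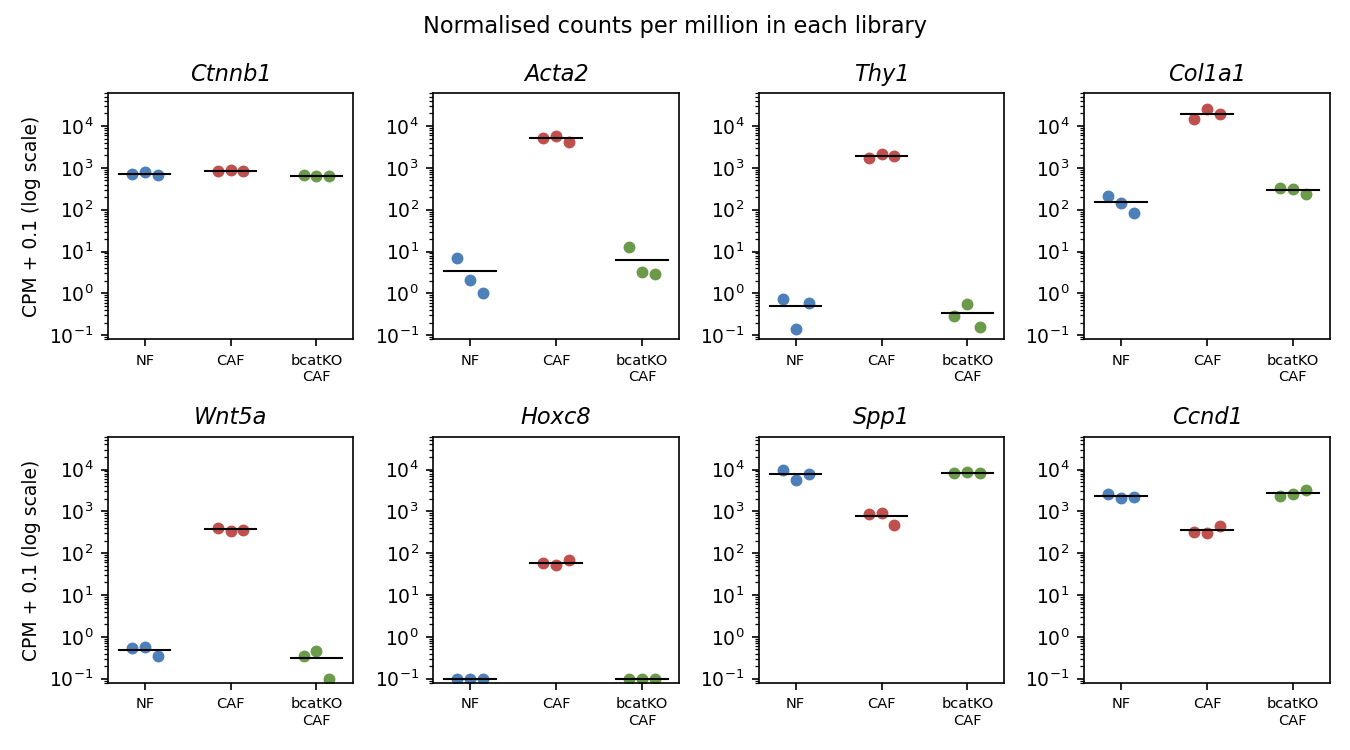
Normalised CPM plus 0.1 of 8 genes on a log axis, with 1 point per library and a line at the mean of each group of 3. Thy1 and Acta2 were at 1960.2 ± 217 and 5059 ± 844 CPM in CAF, far above the other 6 libraries, while Ccnd1 was lower in CAF at 358 ± 70.1 CPM.

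The comparison named in the series title set the libraries labelled beta-catenin-deficient against CAF. In the labelled-deficient libraries, 21 of 25 myofibroblast genes, 15 of 20 collagens and 24 of 26 HOX genes were lower, and 19 of 43 interferon-response genes were higher. Camera called these 4 lists with the preset correlation and not with an estimated correlation (adjusted p = 0.0786, 0.245, 0.0786 and 0.666 with the latter). Thy1 was at 0.239 ± 0.209 CPM there (SD, n = 3) against 1960.2 ± 217 in CAF, Tagln at 0.422 ± 0.275 against 2727 ± 484, and Col1a1 at 293 ± 51.9 against 19927 ± 5611. Ccnd1, which encodes cyclin D1, was at 2719 ± 421 CPM against 358 ± 70.1. At an adjusted p under 0.05, 3079 genes were higher and 3253 lower, of which 2046 and 2261 had an absolute log2 fold change of at least 1. Under total counts as the scaling, 3743 were higher and 2686 lower. Without labelled-deficient replicate 2, the mean there was 0.125 CPM for Thy1 and 0.270 for Tagln.

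Of 25 myofibroblast genes, 21 fell and 1, Cav1, rose (1 higher and 21 lower adjusted over the list alone, with camera adjusted p = 5.49e-10, and adjusted p = 0.0786 with an estimated correlation). Without CAF replicate 3 the list was also called with an estimated correlation (adjusted p = 0.0229). The call of Cav1 was lost without any 1 library of the comparison (adjusted p from 0.0575 to 0.141). Actg2, enteric smooth muscle actin, dropped from 212 ± 72.5 to 0.0731 ± 0.0636 CPM, and Myl9 from 467 ± 133 to 0.216 ± 0.177, where leaving out labelled-deficient replicate 1 gave 0.110 CPM for Actg2 and leaving out replicate 3 gave 0.122 for Myl9. Of 10 markers of pericytes and smooth muscle, 5, Mcam, Abcc9, Myh11, Lmod1 and Ndufa4l2, fell and 1, Cspg4, rose (1 higher and 5 lower adjusted over the list alone, with camera adjusted p = 0.0299, and adjusted p = 0.245 with an estimated correlation), with Lmod1 at 0.230 ± 0.0491 CPM, Myh11 at 0.294 ± 0.126, Mcam at 3.52 ± 0.403 and Cspg4 at 834 ± 295 in the labelled-deficient libraries. Collagens fell in 15 of 20 cases and rose in 2 (2 higher and 15 lower adjusted over the list alone, with camera adjusted p = 1.62e-04, and adjusted p = 0.245 with an estimated correlation), the latter being Col15a1 and Col18a1, with Col18a1 at 2538 ± 692 CPM against 67.9 ± 30.3. Matrix glycoproteins fell in 24 of 40 cases and rose in 6 (7 higher and 24 lower adjusted over the list alone, with camera adjusted p = 1.40e-04, and adjusted p = 0.139 with an estimated correlation). The microfibril genes Mfap4 and Mfap5 had no count in the labelled-deficient libraries and were each at least 1027-fold lower. Lox was at 5.64 ± 3.69 CPM (3.74 without labelled-deficient replicate 1) against 3277 ± 65.7 and Loxl2 at 0.600 ± 0.379 against 729.9 ± 152. Wnt pathway members fell in 23 of 45 cases and rose in 6 (6 higher and 23 lower adjusted over the list alone, with camera adjusted p = 3.03e-04, and adjusted p = 0.139 with an estimated correlation). The 6 that rose became 3 without CAF replicate 3. Wnt5a was at 0.207 ± 0.187 CPM (0.129 without labelled-deficient replicate 2) against 373 ± 28.0, and Wnt7b at 27.2 ± 16.7 against 0.530 ± 0.0806.

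Wnt target genes moved both ways, 5, Notum, Tcf7, Ccnd1, Myc and Fosl1, higher and 7 lower of 19. Adjusted over the list alone, 6 were higher and 7 lower, and camera gave an adjusted p of 0.719. The fry test called the list lower in the labelled-deficient libraries (adjusted p = 0.0254), as 1 of 27 called among 36 lists. The call of Myc was lost without CAF replicate 1, 2 or 3 or labelled-deficient replicate 1, 2 or 3 and with RLE scaling (adjusted p = 0.0515 to 0.163). Lgr5, a receptor that strengthens Wnt signals, had no count in the labelled-deficient libraries and was at least 1942-fold lower than in CAF, where the 3 libraries averaged 106 ± 121 CPM. Without CAF replicate 3 the CAF mean was 35.9 CPM and the limit 625-fold. Nkd1, a Wnt antagonist, was at least 91.5-fold lower. Notum, Tcf7 and Fosl1 were higher, with log2 fold changes of 8.71 ± 0.70, 5.68 ± 0.26 and 2.55 ± 0.32 (SE). Axin2 stood at 1.27 ± 0.647 CPM against 1.04 ± 0.337 (adjusted p = 0.743), and Lef1 at 1.37 ± 0.120 against 2.01 ± 1.61, or 1.08 without CAF replicate 3 (adjusted p = 0.550).

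Interferon-response genes rose in 19 of 43 cases and fell in 0 (19 higher and 0 lower adjusted over the list alone, with camera adjusted p = 5.98e-05, and adjusted p = 0.666 with an estimated correlation), and 24 did not pass the test. The fry test of the list gave an adjusted p of 0.0905. The 19 genes became 11 without CAF replicate 1, 10 without CAF replicate 2 and 12 without labelled-deficient replicate 3, or 8, 0 and 12 adjusted over the list alone. Ifit3 was at 327 ± 128 CPM against 9.50 ± 6.23 in CAF, Rsad2 at 149 ± 64.6 against 3.59 ± 1.75 and Ifi44 at 352 ± 99.1 against 9.93 ± 6.86. Without CAF replicate 3, the CAF means were 5.94 for Ifit3 and 6.01 for Ifi44. Of 19 genes of MHC class I presentation, 11 rose and 3, H2-T22, Pdia3 and Calr, fell (11 higher and 3 lower adjusted over the list alone, with camera adjusted p = 0.0149, and adjusted p = 0.50 with an estimated correlation), with H2-D1 at 419.8 ± 23.5 CPM against 113 ± 40.2, an uncertain value because near-identical class I genes can share its reads. Without CAF replicate 1, 7 of these genes rose. The call of H2-T22 was lost without CAF replicate 1 or 2 or labelled-deficient replicate 1 or 2 (adjusted p = 0.0507, 0.0622, 0.0791 and 0.0610), and that of Pdia3 without CAF replicate 1 or labelled-deficient replicate 1 or 3 (adjusted p = 0.0509, 0.0528 and 0.0603). Cholesterol genes fell in 21 of 25 cases (0 higher and 23 lower adjusted over the list alone, with camera adjusted p = 2.60e-08, and adjusted p = 0.346 with an estimated correlation), with Hmgcs1 at 67.3 ± 12.3 CPM. MAP kinase feedback genes rose in 14 of 21 cases and fell in 3, Spry1, Epha4 and Il1rl1 (15 higher and 3 lower adjusted over the list alone, with camera adjusted p = 0.00180, and adjusted p = 0.245 with an estimated correlation). HOX genes fell in 24 of 26 cases (0 higher and 25 lower adjusted over the list alone, with camera adjusted p = 1.17e-13, and adjusted p = 0.0786 with an estimated correlation), with a median log2 fold change of -6.64, or -5.91 with 9 members at their bound. Kdm5d, a Y-linked gene, had no count in the labelled-deficient libraries and was at 4.20, 25.6 and 28.6 CPM in CAF replicates 1 to 3.

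Among signs of RNA quality, 5 of 10 histone genes, Hist1h1c, Hist1h2bc, Hist1h4i, Hist2h3c2 and H2afx, were lower in the labelled-deficient libraries and 0 higher (0 higher and 5 lower adjusted over the list alone, with camera adjusted p = 0.0403, and adjusted p = 0.346 with an estimated correlation). The call of Hist2h3c2 was lost without CAF replicate 1, 2 or 3 or labelled-deficient replicate 1, 2 or 3, without a filter and with total counts (adjusted p = 0.0636 to 0.121), and that of H2afx without CAF replicate 2 or labelled-deficient replicate 1 or 3 (highest adjusted p = 0.0669). Immediate early genes fell in 9 of 20 cases and rose in 4, Jun, Egr3, Atf3 and Klf4 (4 higher and 9 lower adjusted over the list alone, with camera adjusted p = 0.236, and adjusted p = 0.368 with an estimated correlation). The 9 became 5 without CAF replicate 2 and 4 without labelled-deficient replicate 2, and the call of Egr3 was lost without CAF replicate 2 (adjusted p = 0.0505). Ribosomal protein genes fell in 11 of 50 cases and rose in 3, Rpl10a, Rps13 and Rps27a (0 higher and 3 lower adjusted over the list alone, with camera adjusted p = 0.176, and adjusted p = 0.747 with an estimated correlation). The 11 became 3 without CAF replicate 2 or labelled-deficient replicate 1, 6 without CAF replicate 3 or labelled-deficient replicate 2 and 5 without labelled-deficient replicate 3. The call of Rpl10a was lost without CAF replicate 1 or 3 or labelled-deficient replicate 2 or 3 (adjusted p = 0.0689 to 0.126), that of Rps13 without CAF replicate 1 or 3 or labelled-deficient replicate 1 or 2 and without a filter (adjusted p = 0.0761 to 0.139), and that of Rps27a without CAF replicate 2 or 3 or labelled-deficient replicate 2 or 3 (adjusted p = 0.103 to 0.149). Of the 7 tested among 13 protein-coding genes of the mitochondrial genome, 2, mt-Nd4 and mt-Co1, were higher and 0 lower. Adjusted over the list alone, 0 were higher and 0 lower, with camera adjusted p = 0.366, or 0.747 with an estimated correlation. The calls of mt-Nd4 and mt-Co1 were both lost without any 1 library of the comparison (adjusted p from 0.0556 to 0.105).

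Among the genes with the largest falls were Ndn, an imprinted growth regulator, at least 1892-fold lower, Lrrc17 at least 1631-fold, Adcyap1r1 at least 1345-fold, Siglecg at least 1303-fold and Hoxc8 at least 1041-fold. The limit for Lrrc17 was 959-fold without CAF replicate 3. Among those that rose, Dmp1 was at least 1226-fold higher, Sucnr1, the succinate receptor, at least 1108-fold, Nwd2 at least 567-fold, Rasgrf1 at least 351-fold and Wfdc13 at least 267-fold. The limit for Nwd2 was 206-fold without labelled-deficient replicate 3. Cxcr3 was at least 306-fold higher, a call lost without any 1 CAF library (highest adjusted p = 0.0633, without CAF replicate 2). Nptx1, a neuronal pentraxin, was at 470.2 ± 44.5 CPM against 0.285 ± 0.178. AA467197, Tbx20 and Atp13a4 were higher by 3686-fold (95% counting interval 661 to 145621), 3162-fold (95% counting interval 567 to 124937) and 2758-fold (95% counting interval 494 to 108962). AA467197 and Tbx20 were at least 820.2-fold and 704-fold higher without CAF replicate 2, and Atp13a4 at least 588-fold without CAF replicate 3. Requiring a change beyond 1.5-fold left 3829 genes. Under total counts as the scaling, the median log2 fold change of all genes moved from -0.01 to 0.12.

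**Figure D3:**
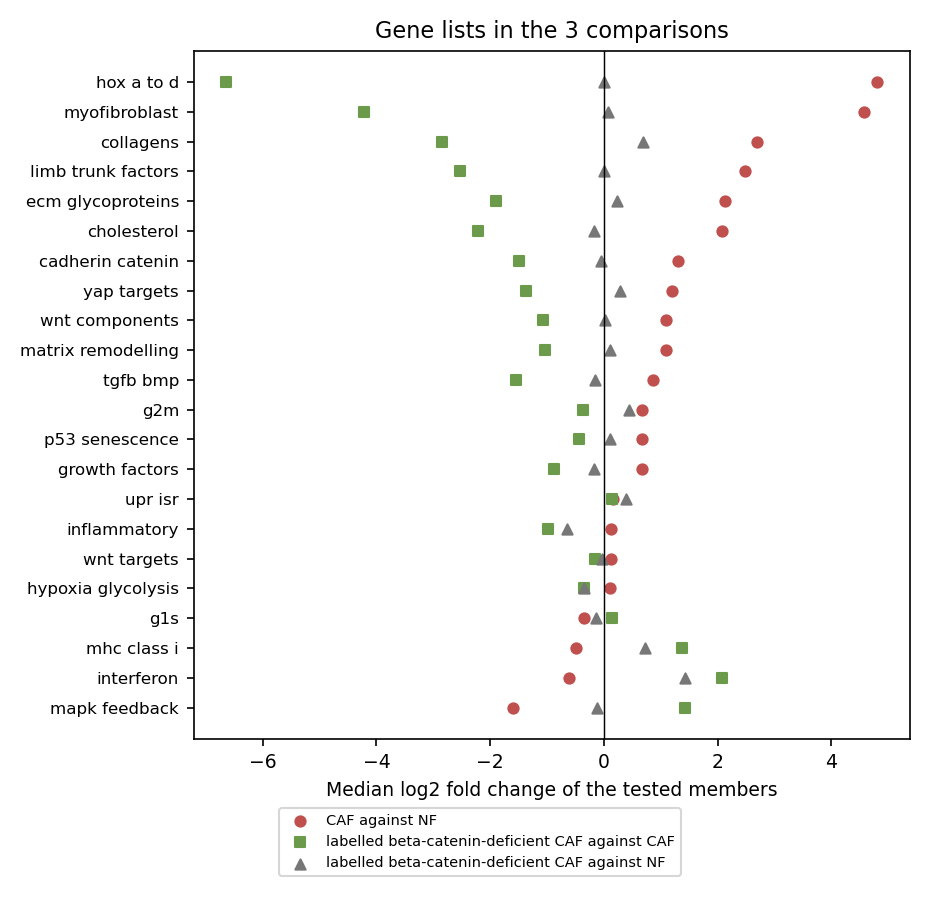
Median log2 fold change of the tested members of each pathway list in the 3 comparisons, with lists ordered by their value in CAF against NF. Myofibroblast genes had medians of 4.56 in CAF against NF and -4.23 in the labelled-deficient libraries against CAF, and HOX genes -6.64 in the latter, a fitted value that became -5.91 with members at their bound.

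Between the labelled-deficient libraries and NF, no gene passed the edgeR quasi-likelihood test. Acta2 was at 6.12 ± 5.50 CPM against 3.27 ± 3.14 in NF, or 2.94 without labelled-deficient replicate 1 and 1.48 without NF replicate 1, Col1a1 at 293 ± 51.9 against 149 ± 66.5, Wnt5a at 0.207 ± 0.187 against 0.386 ± 0.122 and Ccnd1 at 2719 ± 421 against 2327 ± 276. Ifit3 was at 327 ± 128 CPM in the labelled-deficient libraries, and at 221, 45.2 and 5.91 in NF replicates 1 to 3. The smallest adjusted p was 0.601, 702 genes had an unadjusted p under 0.05, and limma-voom called 0 genes. DESeq2 called 6, all higher in the labelled-deficient libraries, which were Masp1, Frzb, Arhgef5, Igsf10, C1s1 and Arrdc4, and edgeR without a filter called 1, Igsf10, with a log2 fold change of 2.20 (adjusted p = 0.0251). Camera called 10 of 36 lists, and 0 with an estimated correlation. The interferon list had a median log2 fold change of 1.42 (camera adjusted p = 1.09e-22, and adjusted p = 0.690 with an estimated correlation), and the collagens 0.68 (camera adjusted p = 1.54e-05, and adjusted p = 0.597 with an estimated correlation), with no member of either called, also adjusted over the list alone. This count of 0 rested on NF replicate 1: without it, 1620 genes were higher and 1039 lower in the labelled-deficient libraries, 2659 in all. Without that library, 39 of 43 interferon-response genes and 9 of 20 collagens were higher, with medians of 2.64 and 0.99 (adjusted p = 0.647 for both with an estimated correlation). The interferon median was 0.94 without NF replicate 3.

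Most genes that separated CAF from NF also separated CAF from the labelled-deficient libraries, which lay on the NF side. With all libraries, no gene was called between the labelled-deficient libraries and NF. The 2 comparisons with CAF therefore largely restate that CAF differed from both groups. Their overlap cannot tell an effect of the genotype from another origin of the CAF cultures. Of 2866 genes higher in CAF than NF, 2561 (89.4%) were lower in the labelled-deficient libraries than in CAF, and of 2847 lower genes, 2363 (83.0%) were higher. Ranked by the smaller of their 2 absolute log2 fold changes, Adcyap1r1, Hoxc8, Hoxc10, Thy1 and Dmrt2 came first in the first direction, and Dmp1, Sucnr1, Rasgrf1, Cxcr3 and AA467197 in the second. No gene was called in the same direction in both. Independent lists of these sizes would share 651 and 612 genes. Across genes, the 2 sets of fold changes had a Pearson r of -0.963 and a covariance of -5.11. The CAF libraries enter both comparisons, and 100 simulated data sets with unchanged groups gave a mean r of -0.497 and a mean covariance of -0.0872, with at most 1 gene called in opposite directions. The observed covariance minus the simulated one was -5.03. With 1 CAF library set against NF and the other CAF libraries against the labelled-deficient ones, r lay between -0.910 and -0.885, and 2809 to 3257 genes were called in opposite directions. The arm of 1 CAF library has no spread of its own and was assumed to vary like the other groups.

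**Figure D4:**
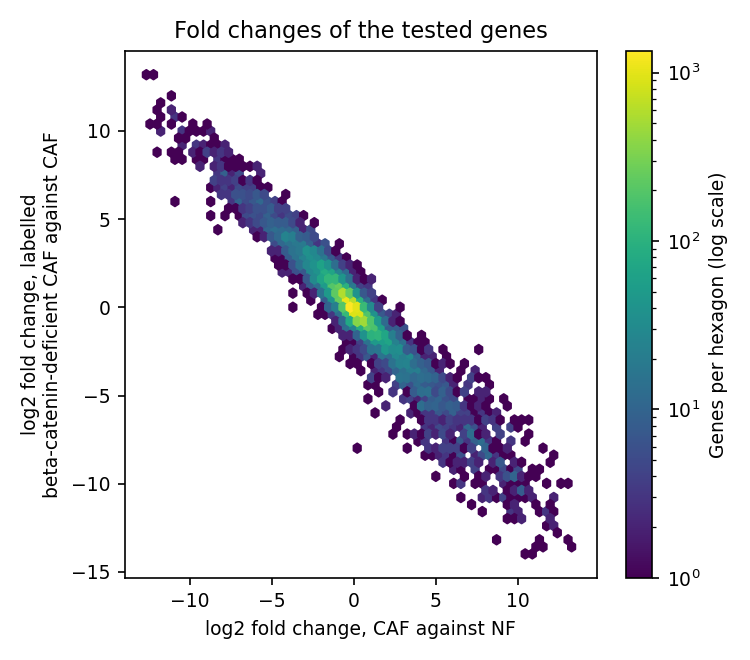
Log2 fold change of each tested gene in CAF against NF (x axis) and in the labelled-deficient libraries against CAF (y axis), as hexagons coloured by the number of genes on a log scale. The points follow a falling line, with a Pearson r of -0.963 across genes.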

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

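The tests with total counts as the scaling, without Gm42418, of Ctnnb1 with limma-voom, of lists against NF, of the sample structure and of genes named after their values were seen were chosen after the data were seen. Counts of called genes in CAF against NF stayed within 1.5 times under RLE, both filters, DESeq2, limma-voom, the 6 samples, total counts and counts without Gm42418, and without single libraries (4685 to 6648); a test beyond 1.5-fold gave 3583. The labelled-deficient libraries against CAF likewise stayed within 1.5 times under these settings, and gave 4966 to 5259 without single libraries and 3829 beyond 1.5-fold; fewer genes pass a stricter test by its construction. Against NF, the count of 0 became 1 without a filter, 6 with DESeq2, and 0 to 2659 without single libraries, the highest without NF replicate 1; the cause was not tested. Ctnnb1 kept its direction, with a log2 fold change of -0.41 without a filter, -0.29 with total counts and -0.45 to -0.41 without single libraries, all no longer called; the estimate shrank with total counts, fewer samples entered without single libraries, and the cause without a filter was not tested. Called lists in CAF against NF numbered 16, 0 with an estimated correlation and 28 with fry. Against CAF they numbered 18, 0 and 27 in the same order, and against NF 10, 0 with an estimated correlation and 0 with fry. Genes called in opposite directions numbered 4076 to 5217 without single libraries, and 2809, 3257 and 2926 with CAF library 1, 2 or 3 alone against NF, an arm assumed to vary like the other groups. Without NF replicate 3, the cholesterol list against NF turned direction, and its median log2 fold change without single libraries ranged from -0.37 to 0.14; the cause was not tested. Over the single genes and lists recomputed, 5906 values under alternatives kept their direction and side of the threshold, 374 lost the call, 59 gained it and 1 turned direction. The first component held 88.0% to 94.0% of the variance without single libraries. At this depth and number of libraries, 28% of simulated genes changed by a log2 of 1 between CAF and NF were recovered. The simulation changed far fewer genes than the 5713 called in the data, which makes the adjusted threshold stricter. This share is therefore not the recovery rate of the real comparison.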

Other observations

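Tests in this part other than those of sample splits, of abundant genes and of marker lists were chosen after the result was seen, as were the counts of markers without single libraries. Several marker genes of other cell types were higher in both NF and the labelled-deficient libraries than in CAF. Chrna1, a muscle acetylcholine receptor subunit, was at 454 ± 83.5 CPM in NF (SD, n = 3), 396 ± 8.30 in the labelled-deficient libraries and 2.29 ± 1.14 in CAF. Acta1, skeletal muscle actin, went the other way, at 0.258 ± 0.115, 0.182 ± 0.135 (0.113 without labelled-deficient replicate 1) and 171 ± 78.0 CPM. Of 4 tested skeletal muscle markers, too few for camera, 2, Acta1 and Mylpf, were higher and 1, Chrna1, was lower in CAF than NF (2 higher and 1 lower adjusted over the list alone). Without CAF replicate 3 or any 1 NF library, 7 markers passed the filter, with 4 or 5 of them higher and 1 lower. Lgals7, an epidermal galectin, was at 45.7 ± 23.8, 36.3 ± 11.4 and 0.135 ± 0.0758 CPM, and Nes, which encodes nestin, at 406 ± 219, 405 ± 123 and 68.4 ± 33.5. Of 5 tested keratinocyte markers, 2, Lgals7 and Sfn, were lower in CAF than NF and 0 higher (0 higher and 3 lower adjusted over the list alone), with camera adjusted p = 0.0654, and adjusted p = 0.216 with an estimated correlation. More keratinocyte markers passed the filter without single libraries, and 2 of 7 were higher without CAF replicate 1, 1 of 7 without CAF replicate 2, 2 of 8 without NF replicate 2 and 3 of 10 without NF replicate 1 or 3. The Schwann and neural list, to which Nes belongs, went both ways: of 11 tested, 4, Pmp22, Mbp, Cdh19 and L1cam, were higher in CAF than NF and 2, Nes and Sox2, lower (4 higher and 2 lower adjusted over the list alone), with camera adjusted p = 0.997, and adjusted p = 0.999 with an estimated correlation. There 2 were higher without CAF replicate 1 or 2, and 4 lower without NF replicate 3. The call of Cdh19 was lost without CAF replicate 1 or 2 or NF replicate 1, 2 or 3 (adjusted p = 0.0513 to 0.124), and that of L1cam without CAF replicate 1 or 2 and with only the 6 samples compared (adjusted p = 0.0570 to 0.159). Laptm5, a leukocyte lysosomal protein, was at 91.9 ± 92.3, 33.1 ± 9.50 and 0.468 ± 0.493 CPM, with means of 39.8 without NF replicate 2 and 0.184 without CAF replicate 2. Krt19, an epithelial keratin, and Lpl, lipoprotein lipase, were higher in CAF, at 26.2 ± 10.3 and 148 ± 64.7 CPM in CAF. Of 4 tested epithelial markers, too few for camera, 3, Krt19, Krt7 and Esrp2, were higher in CAF than NF and 0 lower (3 higher and 0 lower adjusted over the list alone). Of 5 adipocyte markers, 2, Lpl and Pparg, were higher and 1, Cebpa, lower (2 higher and 1 lower adjusted over the list alone), with camera adjusted p = 0.323, and adjusted p = 0.562 with an estimated correlation. The call of Cebpa was lost without CAF replicate 2 or NF replicate 2 (adjusted p = 0.0551 to 0.0698). Of 9 tested leukocyte markers, 6 were lower in CAF than NF and 0 higher (1 higher and 6 lower adjusted over the list alone), with camera adjusted p = 0.0877, and adjusted p = 0.562 with an estimated correlation. Without NF replicate 1, 10 of 12 were lower, with camera adjusted p = 0.00398, and adjusted p = 0.465 with an estimated correlation. Without any other single library of the comparison 3 of 9 to 11 were lower. Of 13 fibroblast markers, 6 were higher and 3 lower in CAF than NF (camera adjusted p = 0.218). Dpt was at 58.6 to 122 CPM in CAF and at most 0.677 in the other groups. Of 7 cartilage and bone markers, 1 was higher and 4 lower (camera adjusted p = 0.0599, and 0.241 with an estimated correlation). Camera called that list without CAF replicate 2 or NF replicate 3 (adjusted p = 0.0486 and 0.0265). Of 9 endothelial markers 4 were higher and 2 lower, and of 9 dermal ones 3 and 3.

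Cdkn2a, which encodes cell cycle inhibitors of senescence, was at 27.3, 40.2 and 41.5 CPM in the CAF libraries and at most 0.19 CPM in the other 6, a region chosen after its values were seen. On the same chromosome, Cdkn2b was at 32.4 to 43.9 CPM in CAF and at most 1.58 in the others, while Mtap, also there, was at 138 to 177 CPM in CAF and 695 to 941 in the others.

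The CAF libraries differed from both other groups. Leaving out the most abundant genes of each library (111 in all) still gave 6277 genes called between the labelled-deficient libraries and CAF. TMM scaling already allows for a share of the counts taken by such genes, so this count cannot decide on that share as the cause. The summed CPM of 4 Y-linked genes was 77.1-fold higher in the lowest CAF library than in the highest labelled-deficient one. Loss of beta-catenin in cells of the same donors would not give this. Summed CPM of the 4 Y-linked genes was 181 and 234 in CAF replicates 2 and 3 and at most 0.450 in the other groups. Xist was at 0.155 and 4.92 CPM in these CAF libraries and at 283 to 923 CPM in the other groups. These CAF libraries thus read as male and the other groups as female. CAF replicate 1 held both, with 34.7 CPM of Y-linked genes and 257 CPM of Xist. Whether sex is the cause of the other differences stays open, because it may also act on autosomal genes. Of the 4924 genes called in both comparisons with CAF, 3.82% lay on X or Y. All tested genes there would make up only 10.3%, so this share cannot decide. Cells of another body position may contribute. Of 26 tested HOX genes, 16 exceeded 1 CPM in every CAF library and stayed under it in the other 6. Limb and trunk factors went both ways, with 16 of 29 higher and 6 lower in CAF than NF. Camera gave that list an adjusted p of 0.00235, or 0.0783 with an estimated correlation. For the 6070 autosomal genes that differed between the labelled-deficient libraries and CAF, the genotype and the origin of the cultures cannot be told apart. Genotype and origin change together. Exchanged CAF and NF labels also stay open: every labelled-deficient library correlated better with every NF library than with any CAF library, by at least 0.127, as such an exchange or cells of another origin might give, while 22 of 25 myofibroblast genes were higher in the libraries labelled CAF.

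Ctnnb1 transcripts were present in the libraries labelled beta-catenin-deficient, at a mean of 644 CPM. Reads from exons outside a deletion might account for it, and this stays open because the counts are per gene. Scaling could also move the difference from CAF: the log2 fold change closest to 0 over 3 scalings was -0.29, with total counts, where the call ended as the estimate shrank from -0.43 ± 0.14 (SE).

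NF replicate 1 lay closer to the labelled-deficient libraries than to the other NF libraries, with interferon list means of 5.51, 3.86 and 1.93 log2 CPM in NF replicates 1 to 3 and 5.35 to 6.38 in the labelled-deficient ones. Its lowest correlation with those libraries exceeded its highest with NF replicates 2 and 3 by 0.0325, as a single wrong label or a culture of another kind might give. An exchange with a labelled-deficient library would leave such a library closer to NF replicates 2 and 3 than to its own group. Each labelled-deficient library instead correlated better with its own group than with NF replicates 2 and 3, by at least 0.0141. This argues against an exchange. That margin is small beside the spread of correlations among NF libraries (0.935 to 0.970), so an exchange is not excluded. Labelled-deficient replicate 3 correlated better with NF replicate 1 (0.989) than with replicates 1 and 2 of its own group (0.978 and 0.982). The Gm42418 share of NF replicate 1, 3.17%, lay between those of NF replicates 2 and 3 (1.5% and 5.34%). It also lay within the 1.01% to 3.58% of the labelled-deficient libraries. These ranges are too wide for the share to decide on ribosomal RNA as the cause. No biological explanation was tested.

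The 6 libraries of each comparison form 10 splits of 3 against 3, too few for a share under 0.05. CAF against NF gave 5713 genes and at most 0 in any other split, with 1 split as large. The labelled-deficient libraries against CAF gave 6332 and at most 0, with 1 split as large. Every other split placed CAF libraries together with libraries of the compared group, which counts their difference as spread. The counts of 0 there therefore cannot decide on chance. For the labelled-deficient libraries against NF, the real split and every other gave 0, so all 10 were as large.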
